A study of Homo sapiens with 6 samples.

How the data were processed

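Gene expression was measured on microarrays in HSC3 cells, an established line of human oral squamous carcinoma, treated with E7386 or with the solvent dimethyl sulfoxide (DMSO). Each group held 3 arrays, one per well. Per the labels' protocols, cells were left for 12 to 24 hours after seeding until about 50% confluent, treated with 0.1 μM E7386 or 0.1% DMSO, and harvested after 48 to 64 hours. Total RNA was labelled with biotin after whole-transcript amplification, per the labels' protocols. The harvest time of each well within this window is not given in the sources used here. The sample titles call the arrays biological replicates, and the labels' growth protocol describes separate wells in triplicate. No label says that the wells came from separate experiments, so the p-values measure the spread between these wells, part of which may be technical.

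The deposited table holds log2 expression values that the authors made with RMA and the affy package, version 1.36.1, per the submitters' processing notes. RMA corrects the background, makes the distributions of the arrays alike by quantile normalization and summarises the probes of a gene on the log2 scale. Values ran from 0.343 to 12.0 over all 6 arrays, and the array medians lay between 3.74 and 3.79. RMA compresses differences of dim genes and gives no detection call, so a gene near the bottom of the scale may be unexpressed. Because the arrays share one distribution, a change in the total RNA per cell leaves no trace. The array design's probe set definition and the genome build are not given in the sources used here, and no coordinates are reported. The table had 23786 rows, 1 per gene identifier, and all of its sample columns were used. The platform annotation gave 1 symbol to 22458 rows and several to none. The other 1328 rows stayed in the fits and are unnamed here.

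The deposited log2 values were used without further normalization. A linear model with the treatment as its only term was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, followed by its empirical Bayes moderation with a constant prior. The two-sided p-values were adjusted over all 23786 rows by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Differences are E7386 minus DMSO on the log2 scale, given with the standard error (SE) of the moderated fit, and n is 3 wells per group throughout. The number of arrays limits the precision: over all genes the median standard deviation (SD) within groups was 0.15. On data simulated for this comparison with the real means and SDs of 23786 genes, the fit found 25.4% of genes changed by 0.5 on the log2 scale, 71.6% of those changed by 1 and 95.5% of those changed by 2, and 8 of its 136 calls were false. Only 67, 67 and 66 genes were changed by these amounts, against 4430 genes called in the real comparison. With so few changed genes the adjustment is stricter, so these shares are not those of the real comparison.

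The gene lists, the rule for the genes named and the alternatives were fixed before the data were examined. The 34 lists were written from general knowledge of the Wnt/β-catenin pathway, squamous carcinoma cells and common drug responses. They include markers of fibroblasts, leukocytes and endothelial cells, which a pure epithelial line should lack. The list of mitochondrially encoded genes had fewer than 5 measured members and was not tested. The other 33 lists were tested against all other genes with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The test was repeated with a correlation estimated from the residuals of each list. A simulated shift of 0.5 in the mitosis list was found, with none of the 31 lists that share no gene with it called. The simulated genes varied independently, whereas the estimated correlation of the real mitosis list was 0.26. This run therefore does not test false calls among correlated genes.

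The rule for the genes named took the 8 largest rises and the 8 largest falls among called genes whose 3 E7386 values all lay on one side of the 3 DMSO values. It left out uncharacterised loci, pseudogenes, small RNA genes and antigen receptor segments. It added up to 4 called members with the largest difference from each list past the threshold and from the Wnt/β-catenin target and partial EMT (epithelial-mesenchymal transition) lists. It always added AXIN2, MYC, CCND1, BIRC5, CD44, CTNNB1, CREBBP, EP300, CDH1, VIM and MKI67. The rule gave 76 genes, of which 1 Y-linked gene is not reported here. Genes named from lists that did not pass the threshold, and those named as exceptions within a list, were chosen after their values were seen.

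The alternatives were renewed quantile normalization, median centring, leaving out dim genes, an intensity trend with or without a robust prior, an ordinary two-sample test, array weights, the replicate number as a block, a 1.5-fold minimum, and leaving out each well in turn. For the lists they were the estimated correlation, limma's fry, the block, leaving out dim genes, quantile normalization and leaving out each well.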

Results

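Expression profiles were obtained from HSC3 cells, a human oral squamous carcinoma line, after treatment with 0.1 μM E7386 or with DMSO, with 3 wells in each group. E7386 is a small molecule described as an inhibitor of the interaction between β-catenin, the transcriptional effector of the Wnt pathway, and its coactivator CREB-binding protein (CBP). The comparison asks which genes differ between treated and solvent-treated cells. Log2 RMA values of 23786 genes were compared, and the values of the median gene averaged 3.75 over the arrays.

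The wells separated by treatment. The first principal component held 58.6% of the variance, with scores of 28.9 to 30.5 for the E7386 wells and -30.6 to -28.9 for the DMSO wells. Pearson correlations across genes were 0.992 to 0.995 between wells of a group and 0.982 to 0.985 between wells of different groups. No columns were identical. In 35.2% of genes the 3 values of one group all lay above those of the other, against 10% that chance gives for 3 against 3.

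Genes of mitosis, DNA replication and lipid synthesis were lower with E7386, and genes of the amino acid and endoplasmic reticulum stress responses were higher. Of the 33 fixed lists tested, 12 passed an adjusted p under 0.05 in camera, 3 of them shifted up and 9 down, and none did with an estimated inter-gene correlation, where the smallest adjusted p was 0.051. Among single genes, 4430 genes passed an adjusted p under 0.05 in limma, 2363 of them higher and 2067 lower with E7386. Of these, 308 rose and 308 fell by at least 2-fold. Without the third E7386 well the count was 2907, 1534 higher and 1373 lower.

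The largest measured rises were those of GULP1, an engulfment adaptor, by 3.32 ± 0.14 (SE) on the log2 scale, and of LCN2, the secreted siderophore-binding protein lipocalin 2, by 3.32 ± 0.21 (limma adjusted p = 5.6e-05 and 1.1e-04). AGR2, a protein disulfide isomerase family member of secretory cells, rose by 3.12 ± 0.26. The noncoding gene LINC03033 rose by 2.98 ± 0.15, and ALDH1L2, a mitochondrial folate enzyme, by 2.64 ± 0.11. ULBP1, a ligand of the NKG2D receptor of natural killer cells, rose by 2.63 ± 0.21, and LAMP3, a lysosomal membrane glycoprotein, by 2.47 ± 0.090. In DMSO these genes lay near or below the level of the median gene, from 2.64 ± 0.41 (SD, n = 3) for ULBP1 to 3.77 ± 0.15 for ALDH1L2, where RMA compresses differences and background cannot be told from expression, so the sizes and order of these rises are uncertain.

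The largest falls started from well above that level. KIF20A, a kinesin of cytokinesis, fell from 8.29 ± 0.12 (SD, n = 3) to 4.81 ± 0.099, an 11.2-fold difference (limma adjusted p = 4.1e-05). AQP3, a water and glycerol channel, fell from 7.91 ± 0.047 to 4.72 ± 0.55. SCD, the desaturase that makes monounsaturated fatty acids, fell from 10.4 ± 0.066 to 7.34 ± 0.16, an 8.23-fold difference. INSIG1, the sterol-regulated retention protein of the endoplasmic reticulum, was 7.06-fold lower, and the basal keratin gene KRT15 was 6.32-fold lower. FAM83D, which encodes a spindle protein, was 5.69-fold lower, TMEM71 5.61-fold, and TNFSF10, which encodes the death ligand TRAIL, 5.55-fold. All 15 of these rises and falls had a limma adjusted p of at most 3.3e-04 and remained called in every alternative fit that tested them.

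**Figure D1:**
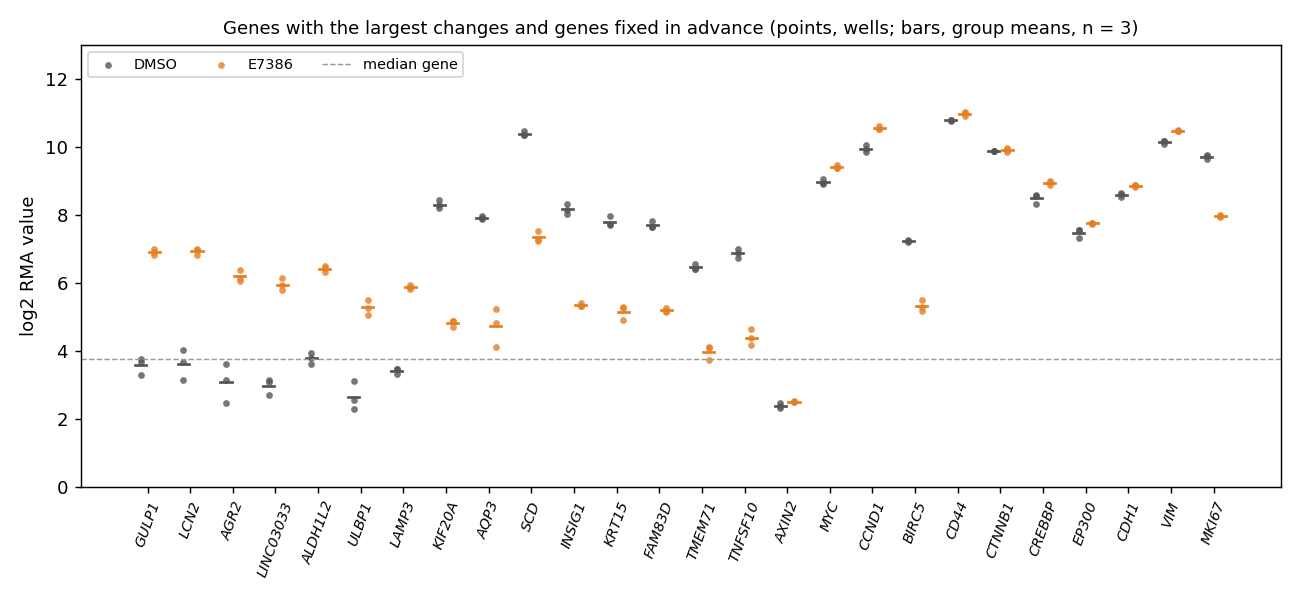
Log2 RMA values (y axis) of the genes with the largest rises and falls and of the genes fixed in advance, in 3 DMSO wells (grey) and 3 E7386 wells (orange); points are wells, bars are group means and the dashed line is the median gene at 3.75. KIF20A falls from 8.29 to 4.81, and CTNNB1 lies at 9.87 and 9.89.

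With the preset correlation, camera also called 4 to 10 lists in each of the 9 splits that mix the 2 groups, which still hold part of the treatment difference.

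**Figure D2:**
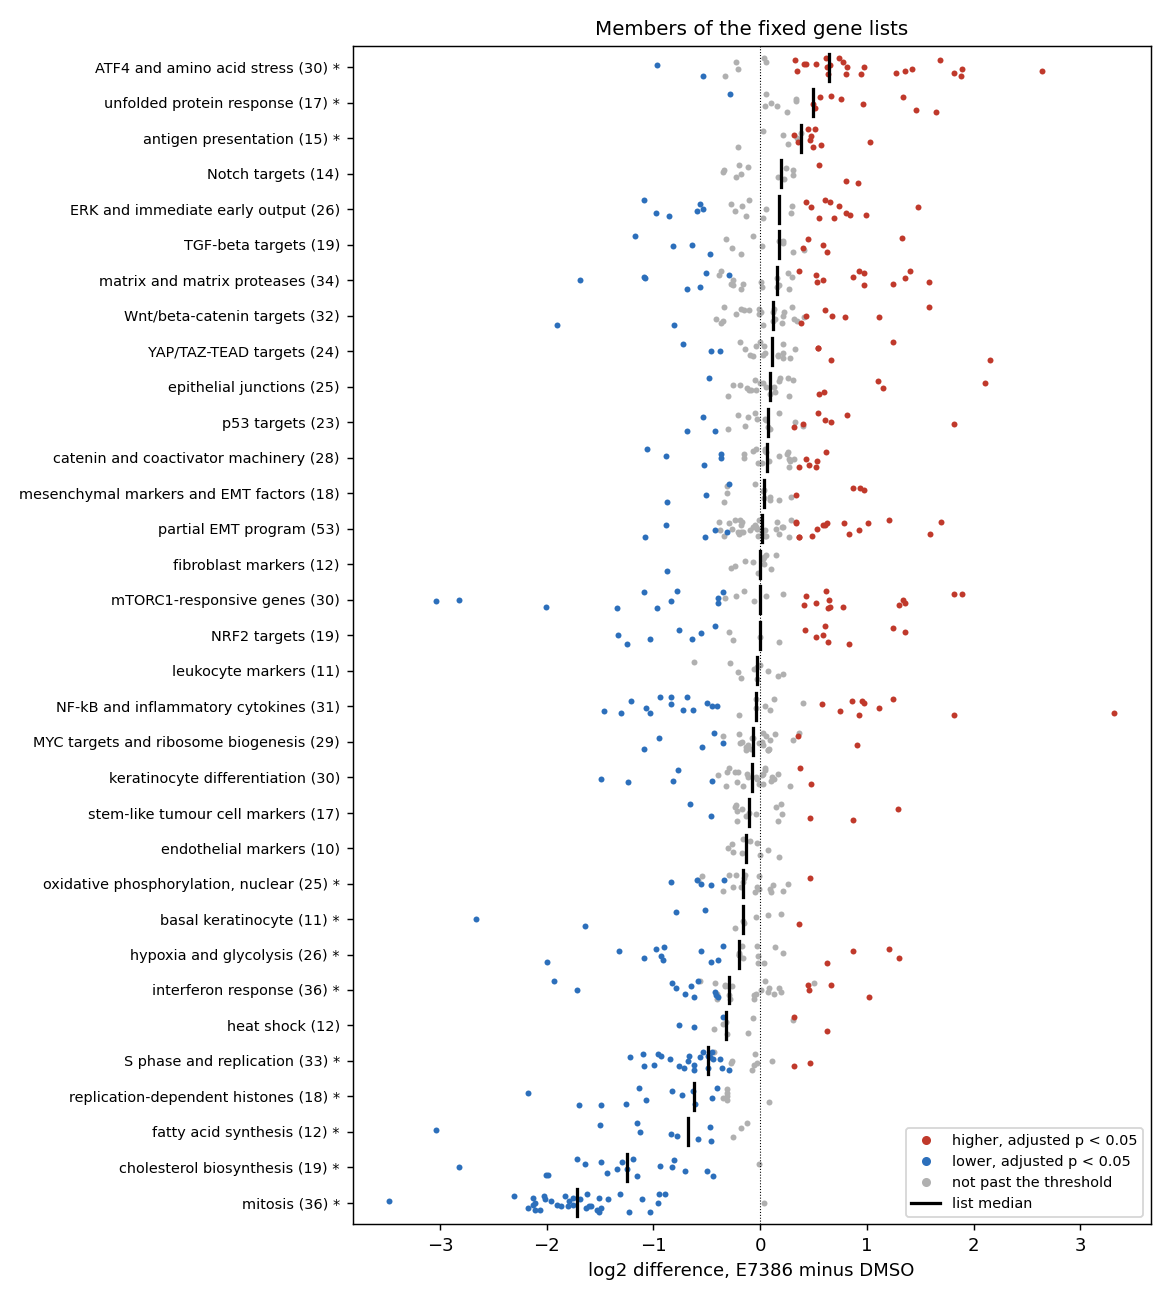
Log2 difference, E7386 minus DMSO (x axis), of each measured member of the fixed lists (y axis, number of members in brackets); red and blue points passed an adjusted p under 0.05, grey points did not, black bars are medians, and an asterisk marks lists past adjusted p under 0.05 in camera. The medians run from -1.72 for mitosis to 0.64 for the ATF4 list.

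Genes of mitosis fell almost without exception. Of 36 measured members 35 fell, none rose, and the median difference was -1.72, a 3.29-fold decrease. The mean over the list went from 8.24 ± 0.075 (SD, n = 3) in DMSO to 6.57 ± 0.043 with E7386. After KIF20A, the largest falls were those of the kinase gene PLK1 at -2.30 ± 0.091 (SE), the cyclin gene CCNB1 at -2.18 ± 0.15 and the kinetochore gene NDC80 at -2.13 ± 0.16. The proliferation marker MKI67 fell by 1.75 ± 0.084. BUB3 was the member not called, at a difference of 0.03 ± 0.083. Camera gave an adjusted p of 5.3e-38 at the preset correlation, and the adjusted p was 0.056 with an estimated correlation. The counts of members were the same when adjusted over the list alone.

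Replication genes fell by less. Of 33 members of the S phase list 23 fell and 2 rose, or 26 and 2 when adjusted over the list alone, with a median of -0.49. The largest falls were those of CDC45, which encodes a subunit of the replicative helicase complex, at -1.22 ± 0.084, and of TK1 and TYMS, enzymes of thymidine nucleotide supply, at -1.10 ± 0.089 and -1.09 ± 0.085. GINS2, of the same complex as CDC45, fell by 1.00 ± 0.12. The 2 that rose were RFC4, by 0.46 ± 0.091, and MCM7, by 0.31 ± 0.087, whose call was lost when any one of the 6 wells was left out (limma adjusted p = 0.060 to 0.15). At the preset correlation the camera adjusted p was 2.2e-11, and the adjusted p was 0.056 with an estimated correlation. Among the replication-dependent histone genes 12 of 18 fell and none rose, or 15 when adjusted over the list alone, with a median of -0.62. H3C8 fell by 2.17 ± 0.18, and H1-5, H4C1 and H2BC14 were at -1.70 ± 0.20, -1.49 ± 0.22 and -1.26 ± 0.12. Histone genes are near-identical copies that can share probes, so the values of single members are uncertain. In camera the adjusted p was 3.4e-09, and the adjusted p was 0.15 with an estimated correlation.

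Genes of lipid synthesis fell together. In the cholesterol biosynthesis list 18 of 19 measured members fell, also when adjusted over the list alone, with a median of -1.25, a 2.38-fold decrease. The largest falls were those of INSIG1 at -2.82 ± 0.10, the isopentenyl diphosphate isomerase gene IDI1 at -2.01 ± 0.11, the sterol carrier gene STARD4 at -1.99 ± 0.082 and the mevalonate kinase gene MVK at -1.71 ± 0.12. PMVK was not called, at a difference of -0.010 ± 0.12 and a DMSO level of 4.12. Tested with camera, the list had an adjusted p of 1.5e-17, and the adjusted p was 0.056 with an estimated correlation. In the fatty acid synthesis list 9 of 12 fell and none rose, or 10 when adjusted over the list alone, with a median of -0.68. SCD led at -3.04 ± 0.11, followed by the phosphatidate phosphatase gene LPIN1 at -1.50 ± 0.11, the transcription factor gene SREBF1 at -1.15 ± 0.084 and the fatty acid synthase gene FASN at -1.13 ± 0.089. The camera adjusted p was 3.6e-09, and the adjusted p was 0.056 with an estimated correlation.

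Genes of the amino acid stress response rose. Of 30 members of the ATF4 list 23 rose and 2 fell, with the same counts when adjusted over the list alone, and the median was 0.64. Besides ALDH1L2, the largest rises were those of the pseudokinase gene TRIB3 by 1.89 ± 0.12, of STC2, which encodes the secreted protein stanniocalcin 2, by 1.88 ± 0.10, and of SESN2, which encodes a leucine sensor upstream of mTORC1, by 1.82 ± 0.089. The 2 that fell were DDIT4, by 0.97 ± 0.11, and ATF3, by 0.53 ± 0.14. The call of ATF3 was lost when any one well except the first E7386 well was left out (limma adjusted p = 0.072 to 0.11). The ATF4 transcript differed by -0.20 ± 0.10 and was not called (limma adjusted p = 0.24). The camera adjusted p of the list was 3.1e-12, and the adjusted p was 0.051 with an estimated correlation.

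In the unfolded protein response list 9 of 17 members rose and 1 fell, or 11 and 1 when adjusted over the list alone, with a median of 0.50. DNAJB9, a cochaperone gene, rose by 1.65 ± 0.19, HERPUD1 and SEL1L, which act in the degradation of misfolded proteins, by 1.46 ± 0.085 and 0.97 ± 0.088, and the transcription factor gene XBP1 by 1.34 ± 0.096. The chaperone gene HSPA5 rose by 0.66 ± 0.090, and CALR fell by 0.28 ± 0.080, a call lost when any one of the 6 wells was left out (limma adjusted p = 0.089 to 0.14). At the preset correlation the camera adjusted p was 4.7e-07, and the adjusted p was 0.18 with an estimated correlation.

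Antigen presentation genes shifted up and interferon response genes shifted down. In the antigen presentation list 9 of 15 members rose and none fell, or 12 and 1 when adjusted over the list alone, with a median of 0.39. CD274, which encodes the checkpoint ligand PD-L1, rose by 1.03 ± 0.11, HLA-E by 0.57 ± 0.10, B2M, the light chain of class I molecules, by 0.51 ± 0.098 and TAPBP, a peptide-loading factor, by 0.50 ± 0.099. HLA genes can share probes. In camera the adjusted p was 7.4e-06, and the adjusted p was 0.15 with an estimated correlation. In the interferon response list 11 of 36 fell and 4 rose, or 14 and 5 when adjusted over the list alone, with a median of -0.30. IFIT1 fell by 1.93 ± 0.24, IFI44 fell by 1.72 ± 0.14 and SAMD9 fell by 0.83 ± 0.12, while IRF9, a subunit of the interferon-activated transcription factor, rose by 1.02 ± 0.10. IFIT1 lay near the median gene in DMSO, at 3.87, and below it with E7386, at 1.94, so the size of its fall is uncertain. Tested with camera, the list had an adjusted p of 0.013, and the adjusted p was 0.40 with an estimated correlation.

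The hypoxia and glycolysis, basal keratinocyte and oxidative phosphorylation lists also shifted down. In the first, 11 of 26 members fell and 4 rose, with the same counts when adjusted over the list alone and a median of -0.20. EGLN3, an oxygen sensor, fell by 2.00 ± 0.15 and the aldolase gene ALDOC by 1.32 ± 0.19, while the glucose transporter gene SLC2A3 rose by 1.31 ± 0.18 and the collagen hydroxylase gene P4HA2 by 1.21 ± 0.084. SLC2A3 lay below the median gene in both groups, at 2.27 in DMSO and 3.58 with E7386, so the size of its rise is uncertain. The camera adjusted p was 0.020, and the adjusted p was 0.15 with an estimated correlation. In the basal keratinocyte list 4 of 11 fell and 1 rose, or 5 and 1 when adjusted over the list alone, with a median of -0.16 and a mean of -0.51. Those that fell were KRT15 at -2.66 ± 0.13, KRT14 at -1.64 ± 0.11, KRT5 at -0.79 ± 0.081 and CAV1, a caveolin gene, at -0.51 ± 0.089, and the laminin gene LAMB3 rose by 0.36 ± 0.087. The call of LAMB3 was lost when any one well except the third DMSO well was left out (limma adjusted p = 0.060 to 0.084). The integrin genes of the list were not called. At the preset correlation the camera adjusted p was 0.021, 0.055 without the third DMSO well, and the adjusted p was 0.40 with an estimated correlation.

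In the oxidative phosphorylation list 5 of 25 members fell and 1 rose, or 9 and 1 when adjusted over the list alone, with a median of -0.16. SDHD, a subunit of complex II, fell by 0.84 ± 0.11, ATP5F1C of the ATP synthase by 0.60 ± 0.099 and COX6C of complex IV by 0.56 ± 0.12, while COX5A of complex IV rose by 0.47 ± 0.10. In camera the adjusted p was 0.045, and the adjusted p was 0.42 with an estimated correlation. The preset call was lost without the first DMSO well (adjusted p = 0.062), the second DMSO well (0.14), the first E7386 well (0.093) or the third E7386 well (0.082). COX6C lost its call without the first E7386 well (limma adjusted p = 0.054) or the second (0.059). COX5A lost it without the first DMSO well (limma adjusted p = 0.0504), the third DMSO well (0.055), the second E7386 well (0.071) or the third (0.060).

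**Figure D3:**
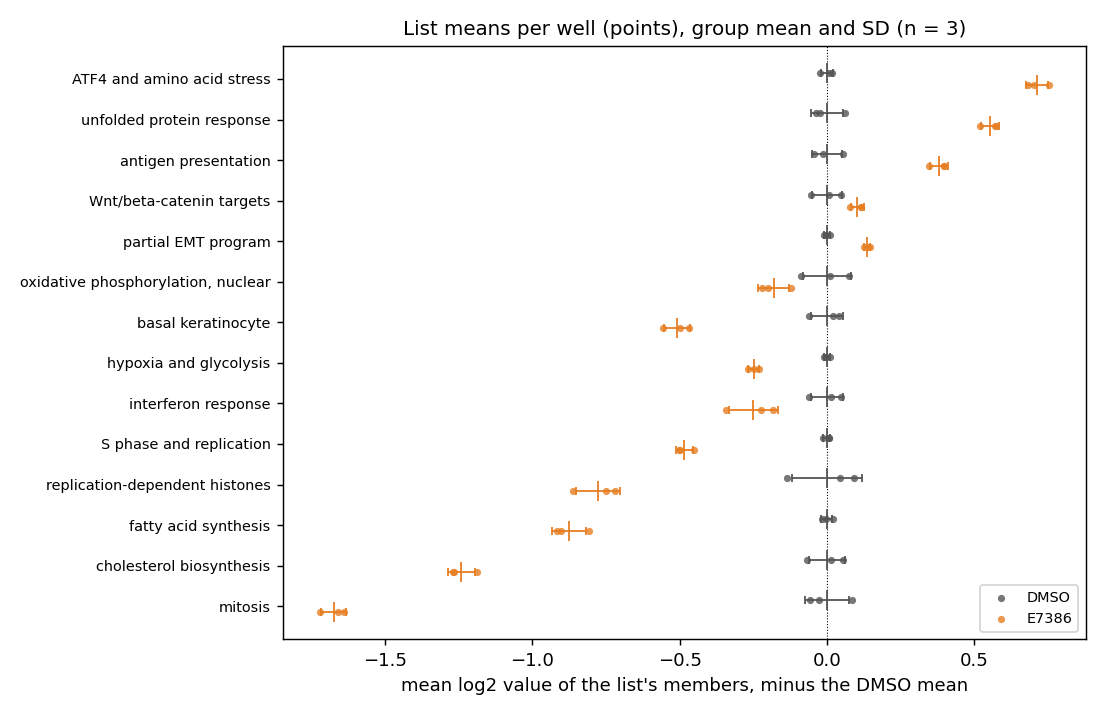
Mean log2 value over the members of each list, minus the mean of the DMSO wells (x axis), for the 12 lists past the threshold and the Wnt/β-catenin target and partial EMT lists (y axis); points are wells, ticks and whiskers are means and SD of 3 wells per group. Mitosis lies lowest with E7386, at 6.57 against 8.24 in DMSO before subtraction.

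The Wnt/β-catenin target list did not shift down. Of 32 measured members 7 rose, 2 fell and 23 were not called, or 9 and 2 passed when adjusted over the list alone, and the median difference was 0.13. BIRC5, which encodes the mitotic protein survivin and is also in the mitosis list, fell by 1.90 ± 0.10, and KREMEN1, a receptor of the Wnt antagonist Dickkopf, fell by 0.81 ± 0.13. PLAUR, the urokinase receptor gene, rose by 1.58 ± 0.086 and the growth factor gene BMP4 by 1.12 ± 0.14. CCND1, which encodes cyclin D1, rose by 0.61 ± 0.092 (limma adjusted p = 0.0040) and MYC by 0.43 ± 0.086 (limma adjusted p = 0.012, 0.054 without the third E7386 well). AXIN2, a feedback target of the pathway, lay below the median gene at 2.37 ± 0.071 (SD, n = 3) in DMSO and 2.50 ± 0.023 with E7386, and was not called (limma adjusted p = 0.39). Other uncalled members also lay below the median gene in DMSO, among them LGR5 at 1.65, NOTUM at 2.97, NKD1 at 3.51 and SP5 at 3.56. A fall of such dim members could be compressed, so they are a weak test of reduced Wnt output. Among members above the median gene in DMSO, LEF1 rose by 0.80 ± 0.11 from 4.56 (limma adjusted p = 0.0030). RNF43, at 5.88, differed by 0.0070 ± 0.10 and was not called. The 2 that fell, BIRC5 and KREMEN1, also lay above the median gene in DMSO. CD44 differed by 0.20 ± 0.083 and was not called (limma adjusted p = 0.15). The camera adjusted p of the list was 0.070, and the adjusted p was 0.35 with an estimated correlation. It was 0.026 at the preset correlation, in the upward direction, when genes below the median were left out.

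The transcripts of the compound's reported targets changed little or not detectably. CTNNB1, which encodes β-catenin, differed by 0.020 ± 0.082 (limma adjusted p = 0.91) and turned to -0.011 without the second E7386 well. CREBBP, which encodes CBP, rose by 0.45 ± 0.10 (limma adjusted p = 0.020). Its call was lost without the second DMSO well (adjusted p = 0.051), the first E7386 well (0.064) or the third E7386 well (0.076). Its paralog EP300 differed by 0.27 ± 0.099 and was not called (limma adjusted p = 0.11). In the whole list of catenin and coactivator machinery 6 of 28 members rose and 5 fell, or 8 and 5 when adjusted over the list alone, with a median of 0.067 and a camera adjusted p of 0.22. The adjusted p was 0.40 with an estimated correlation. Among those that fell were CTNND1, which encodes p120-catenin, by 1.06 ± 0.28 and CTNNBIP1, an inhibitor of β-catenin binding to TCF factors, by 0.89 ± 0.12. The call of CTNND1 was lost when any one well except the third DMSO well was left out (limma adjusted p = 0.070 to 0.11). The corepressor gene TLE3 rose by 0.62 ± 0.11.

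Genes of the epithelial and mesenchymal states went both ways. In the partial EMT list 16 of 53 members rose and 5 fell, or 17 and 8 when adjusted over the list alone, with a median of 0.015 and a camera adjusted p of 0.15. The adjusted p was 0.40 with an estimated correlation. IL32 rose by 1.69 ± 0.13, the protease inhibitor gene SERPINE2 by 1.59 ± 0.11 and P4HA2 by 1.21 ± 0.084, while the metalloproteinase inhibitor gene TIMP3 fell by 1.08 ± 0.13. VIM, the gene of the mesenchymal filament protein vimentin, rose by 0.33 ± 0.080 (limma adjusted p = 0.026), and its call was lost when any one of the 6 wells was left out (adjusted p = 0.055 to 0.088). CDH1, the gene of E-cadherin, differed by 0.26 ± 0.085 and was not called (limma adjusted p = 0.081). In the list of mesenchymal markers and EMT factors 4 of 18 rose and 3 fell, also when adjusted over the list alone, with a camera adjusted p of 0.61. CDH2, the gene of N-cadherin, rose by 0.97 ± 0.087 (limma adjusted p = 4.3e-04), and FN1, the gene of fibronectin, fell by 0.50 ± 0.093 (0.0090). ZEB1 rose by 0.94 ± 0.20 (limma adjusted p = 0.016) from a DMSO level of 2.94, below the median gene. In the epithelial junction list 5 of 25 rose and 1 fell, or 6 and 1 when adjusted over the list alone, with a camera adjusted p of 0.067, which was 0.047 without the second DMSO well and 0.030 without the second E7386 well. With all wells the adjusted p was 0.35 with an estimated correlation. The claudin genes CLDN1 and CLDN7 rose by 2.11 ± 0.13 and 1.15 ± 0.098 and the occludin gene OCLN by 1.11 ± 0.16.

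Several of the remaining lists held many called genes in both directions and did not pass in camera. In the list of NF-κB and inflammatory genes 10 of 31 rose and 14 fell, or 11 and 14 when adjusted over the list alone (camera adjusted p = 0.61). The chemokine genes CXCL8 and CXCL2 and the cytokine gene TNF fell, at -1.46 ± 0.10, -1.21 ± 0.14 and -1.30 ± 0.092, while IL24 rose by 1.82 ± 0.095, the acute phase gene SAA2 by 1.12 ± 0.21 and the NF-κB subunit gene RELB by 0.97 ± 0.11. In the list of ERK and immediate early output 11 of 26 rose and 6 fell, or 13 and 6 when adjusted over the list alone (camera adjusted p = 0.12). ETV5 and ETV4, transcription factor genes induced by ERK signalling, rose by 1.48 ± 0.10 and 1.00 ± 0.088 and the feedback inhibitor gene SPRY2 by 0.81 ± 0.11, while FOS, JUN and EGR1 fell, at -1.09 ± 0.11, -0.86 ± 0.11 and -0.59 ± 0.10. In the mTORC1 list 13 of 30 rose and 11 fell, also when adjusted over the list alone (camera adjusted p = 0.68). Of its members shared with the ATF4 list 10 of 14 rose and 1 fell, and all 6 shared with the cholesterol or fatty acid lists fell. In the list of matrix and matrix proteases 12 of 34 rose and 7 fell, or 15 and 9 when adjusted over the list alone (camera adjusted p = 0.12). The collagenase gene MMP13 fell by 1.68 ± 0.15, and ADAM12, which encodes a membrane metalloproteinase, rose by 1.41 ± 0.11. In the NRF2 list 8 of 19 rose and 7 fell, or 8 and 8 when adjusted over the list alone (camera adjusted p = 0.92).

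In the p53 target list 7 of 23 rose and 3 fell, or 9 and 4 when adjusted over the list alone, with a camera adjusted p of 0.14. CDKN1A, which encodes the cell cycle inhibitor p21, rose by 0.40 ± 0.11 (limma adjusted p = 0.042), a call lost when any one well except the second DMSO well was left out (0.092 to 0.12). In the list of YAP/TAZ-TEAD targets 5 of 24 rose and 3 fell, or 7 and 3 when adjusted over the list alone (camera adjusted p = 0.11), with ANKRD1 at 2.16 ± 0.13 from a DMSO level of 2.91, below the median gene. The TGF-β list had 5 rises and 4 falls among 19 members (0.36), the Notch list 3 and 0 among 14 (0.30), and the stem-like marker list 3 and 2 among 17 (0.68). The keratinocyte differentiation list had 2 rises and 5 falls among 30 (0.12), the list of MYC targets and ribosome biogenesis 2 and 5 among 29 (0.39), and the heat shock list 2 and 3 among 12 (0.12), all as camera adjusted p. When adjusted over the list alone, the counts higher and lower were 7 and 4 for TGF-β, 4 and 6 for MYC targets and 2 and 7 for heat shock, and did not change for the Notch, stem-like, keratinocyte differentiation, fibroblast, leukocyte and endothelial lists. The keratinocyte differentiation list passed downward when genes below the median were left out (adjusted p = 0.011). With all genes its adjusted p was 0.40 with an estimated correlation. The test and the median differed in sign for the stem-like, NRF2 and fibroblast lists. The test and the mean did so for the mTORC1, NF-κB and NRF2 lists, although the fibroblast mean of -0.10 went with its test. The fibroblast, leukocyte and endothelial marker lists had no member that rose, and 1 member, FAP, that fell by 0.87 ± 0.13 from a DMSO level of 3.05, below the median gene. Their camera adjusted p values were 0.48, 0.62 and 0.36.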

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

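All alternatives of this part were planned. Of the 70 called genes named by the rule, 5 lost their call under at least one alternative: COX6C, COX5A, MYC, CREBBP and VIM. Of the 50 called genes named outside the rule and followed through the alternatives, 9 did: ATF3, CALR, CDKN1A, CTNND1, GARS1, LAMB3, MCM7, SARS1 and SAA2, the last by the ordinary test alone (0.078). No direction turned among these called genes. LEF1, CDH2, ZEB1 and FN1, also named outside the rule, were not followed in this way. The uncalled CTNNB1 turned to -0.011 without the second E7386 well and ranged up to 0.049 with another well left out. The uncalled PMVK turned to 0.011 with array weights and ranged from -0.13 to 0.057 when 1 well was left out. Some uncalled genes passed with an intensity trend in the prior: CD44 (limma adjusted p = 0.0099), EP300 (0.031), CDH1 (0.0082) and TIPARP (0.035). Leaving out the genes below the median let CD44 (limma adjusted p = 0.049), EP300 (0.038), CDH1 (0.021) and SMPDL3A (0.048) pass. CDH1 also passed without the dimmest 25% of genes (limma adjusted p = 0.0498) and by the ordinary two-sample test (adjusted p = 0.040). The count of 4430 genes was 3498 to 5496 under the other normalizations, filters, priors, weights, the block and the ordinary test. It was 2171 (1176 higher, 995 lower) with a 1.5-fold minimum, which is stricter by construction, and 2907 to 3635 (1534 to 1978 higher, 1373 to 1657 lower) when 1 well was left out. The share of higher genes stayed between 51.5% and 54.9%, and the median difference over all genes between -0.028 and 0.024. With an estimated correlation 0 lists passed, as against 12. The adjusted p was then 0.056 for mitosis, S phase, cholesterol and fatty acid synthesis, 0.051 for ATF4, 0.15 for histones, hypoxia and antigen presentation, 0.18 for the unfolded protein response, 0.40 for basal keratinocytes and interferon and 0.42 for oxidative phosphorylation; a correlation estimated from 4 residual degrees of freedom is itself uncertain. By fry, which does not compare a list with other genes, 27 lists passed, among them Wnt/β-catenin targets (0.0091) and partial EMT (6.7e-04). Without the genes below the median, Wnt/β-catenin targets passed upward (0.026), keratinocyte differentiation passed downward (0.011) and oxidative phosphorylation did not pass (0.068). When 1 well was left out, 11 to 13 lists passed, with epithelial junctions added upward without the second DMSO well (0.047) or the second E7386 well (0.030). The adjusted p then ranged from 0.012 to 0.055 for basal keratinocytes, 0.017 to 0.14 for oxidative phosphorylation, 0.0036 to 0.040 for interferon, 0.016 to 0.033 for hypoxia, 0.055 to 0.19 for Wnt/β-catenin targets and 0.093 to 0.24 for partial EMT, and was at most 4.8e-05 for the other 8 lists. The replicate number was left out of the main fit because no label says that wells of the same number were handled together. Same-numbered wells deviated from their group means with correlations of 0.051, 0.12 and -0.0077, and 4 of the 6 wells correlated best with the well of their own number. With the replicate block 3701 genes passed, 2000 higher and 1701 lower, and the same 12 lists; the calls of VIM (0.065), GARS1 (0.066), LAMB3 (0.068), SARS1 (0.073), CDKN1A (0.077), MCM7 (0.094) and CALR (0.096) were lost. Scanner intensities were not used here, so the background correction and a slide effect were not varied. The causes of the lost calls were not tested. Signal limits the dim genes: 476 of the 4430 called genes lay below the median gene.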

Other observations

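The lists, families and tests of this part were chosen after the main results had been seen, except the splits of the wells, whose expected outcome was written before; the outcomes expected of the liver X receptor and aryl hydrocarbon receptor lists were written before their values were seen.

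Genes that load amino acids onto transfer RNA went both ways. Of 19 measured cytosolic aminoacyl-tRNA synthetase genes 9 rose and 2 fell, or 10 and 3 when adjusted over the list alone. The median was 0.30 (camera adjusted p = 0.013 over the 4 lists added, and adjusted p = 0.56 with an estimated correlation). Of the 9 that rose, AARS1, GARS1, SARS1 and WARS1 are also in the ATF4 list, so the shift partly restates that list's. GARS1 lost its call when any one well except the first DMSO well was left out (limma adjusted p = 0.054 to 0.097), and SARS1 when any one of the 6 was (0.052 to 0.12). Without these 4 genes 5 of 15 rose and 2 fell, with a median of 0.14, and the list did not pass (limma's camera, unadjusted p = 0.12, as against 0.0032 with them). WARS1 rose by 0.80 ± 0.080 (SE), AARS1 by 0.74 ± 0.082 and MARS1 by 0.62 ± 0.099, while QARS1 fell by 0.67 ± 0.082. Of 16 mitochondrial synthetase genes 1 rose and 4 fell, or 4 and 8 when adjusted over the list alone, with a median of -0.20 (limma's camera, adjusted p = 0.16). PARS2 rose by 0.95 ± 0.10 and SARS2 fell by 0.99 ± 0.091. The 3 microRNA genes MIR27A, MIR23A and MIR24-2, which lie in one cluster, rose by 2.54 ± 0.15, 1.70 ± 0.18 and 1.75 ± 0.17 (limma adjusted p = 9.0e-05, 9.3e-04 and 7.1e-04). These values are gene-level array signals and do not measure the mature microRNAs.

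Among 394 groups of genes that share the letters of their symbols, PRPF, pre-mRNA splicing factors, was the one past an adjusted p of 0.05 in camera (adjusted p = 0.039, and adjusted p = 0.91 with an estimated correlation), with 4 of 11 lower and none higher. PRPF31 fell by 0.85 ± 0.091. In the SRSF group of splicing factors 6 of 13 fell and 1 rose, led by SRSF1 at -1.03 ± 0.089 (adjusted p = 0.065). Of 15 kallikrein genes 7 fell and none rose, led by KLK5, a skin serine protease gene, at -1.24 ± 0.090 (adjusted p = 0.065). In the KIF group of kinesins 14 of 43 fell and 3 rose (adjusted p = 0.065), and some of those that fell, KIF20A among them, are also in the mitosis list. In the TMED group of cargo receptors between endoplasmic reticulum and Golgi 4 of 12 rose and none fell, led by TMED9 at 0.82 ± 0.11 (adjusted p = 0.074). For each of these other groups too the adjusted p was 0.91 with an estimated correlation.

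The fall of the mitosis genes had a median of -1.72 over 36 members. Random lists of the same size matched on mean expression never had a median below -0.28 in 10000 draws. RMA makes the distributions of the arrays alike, so a large shift common to genes of that brightness was unlikely before any draw. The draws therefore decide little about such a shift. They also cannot address an array or normalization effect particular to these genes. Fibroblasts, leukocytes or endothelial cells in the treated wells are argued against, since 0 of 33 of their markers were called higher and 1 lower. Their list means stayed low, from 2.63 to 2.53, 2.90 to 2.81 and 2.29 to 2.18. Other epithelial cells were not tested for. A difference in harvest time or density between the wells of the groups stays open: 0 samples have a harvest time or density of their own in the labels, and the window ran from 48 to 64 hours. An effect of E7386 on dividing cells, the biological difference that the design names, may also account for it and cannot be told apart from such a growth difference here.

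The cholesterol and fatty acid synthesis lists joined had a median of -1.13 over 31 members, and matched random lists never had one below -0.31 in 10000 draws. As for the mitosis list, the draws decide little about a shift common to genes of that brightness. An array effect particular to these genes is left unaddressed. One hypothesis is sterol excess, which could lower these genes and activate the liver X receptor. The 6 measured targets of that receptor had a median of -0.091 ± 0.15 (SD over 3 E7386 wells; adjusted p = 0.67 in limma's camera), under the bound of 0.1 written before. That bound was unsuited, because members went both ways when adjusted over the list alone: MYLIP fell by 0.60 ± 0.10 and SMPDL3A was at 0.41 ± 0.15. Sterol excess therefore stays open, as does a direct effect of E7386, which was not tested.

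CYP1A1 and CYP1B1, enzyme genes induced by the aryl hydrocarbon receptor, rose by 2.33 ± 0.27 and 1.82 ± 0.12 (limma adjusted p = 0.0013 and 1.6e-04). If that receptor was activated, its other targets might rise too. AHRR, its feedback repressor gene, rose by 0.94 ± 0.12, but NQO1 fell by 0.56 ± 0.090 and TIPARP was at -0.26 ± 0.11. The median of the 7 other targets was -0.22 ± 0.17 (SD over 3 E7386 wells; adjusted p = 0.56 in limma's camera), under the bound of 0.1 written before. That bound was unsuited as well, since members were called in both directions and 3 of the 7 lay below the median gene, so activation of the receptor stays open.

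Of the 10 splits of the 6 wells into 3 and 3, 1, the real one, gave 4430 called genes, and the highest of the others gave 0. In those 9 mixed splits 439 to 942 genes had an unadjusted p under 0.05, and the ordinary two-sample test called at most 1. Each mixed split puts treated and DMSO wells in one group, so the treatment difference adds to the spread within groups. Few calls of genes were to be expected there, and their number does not measure how many of the 4430 calls are false. For the lists, 1 of 10 splits, the real one, gave 12 calls and the highest of the others 10. With 10 splits the share cannot fall under 0.05.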
